A study of Homo sapiens with 6 samples.

How the data were processed

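Gene expression was measured on 6 Affymetrix oligonucleotide arrays, each hybridised with biotin-labelled RNA from CD34+ cells of human umbilical cord blood. RNA went through 2 rounds of amplification before labelling, per the labels' protocols. The deposited values are log2 expression per probe set, and per the submitters' processing notes they were made with RMA in Affymetrix Expression Console. RMA corrects the background, normalises probe intensities across arrays and summarises the probes of a probe set into 1 log2 value. The genome build behind the annotation is not given in the sources used here, and no coordinates are reported.

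The table held 54675 probe sets. The 62 control probe sets were left out of all gene counts. In the platform's annotation table, 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none, and genes were named only from those with 1 symbol. The Entrez identifier of 41037 of the 41091 was found in the reference gene table, and 0 symbols changed. A probe set was kept when its mean over the 6 arrays was at or above 6.47 log2, the median of all probe sets that are not controls. Where several kept probe sets measured a gene, the one with the highest mean over the 6 arrays stood for it. This left 12605 genes, of which 5628 had more than 1 kept probe set.

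Arrays were grouped by the label of each sample, with 1 array per condition, so the log2 difference between 2 arrays has no replicate error. Such differences were counted at a threshold of 2-fold and carry no p-value. Tests across arrays used limma (version 3.58.1, R version 4.3.3) with lmFit and eBayes on the log2 values, 2-sided, with Benjamini-Hochberg adjustment over all 12605 genes at a threshold of 0.05. There were 3 fits. The first set the 5 dmPGE2 arrays against the lone vehicle array, which was assumed to vary like the others. The second fitted a slope on the log2 of minutes of dmPGE2 plus 1 over all 6 arrays. The third fitted a slope on the log2 of minutes over the 5 dmPGE2 arrays. The labels do not say whether the 6 arrays came from separate donors or cultures, so p-values measure only the spread among these arrays.

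The comparisons, their tests, the rule for named genes, the 25 gene lists and the alternative settings were fixed before the data were examined. A list was described by its median log2 difference from vehicle and by the percentile of that median among 10000 random lists of the same size and similar mean expression. The trend of a list's mean log2 value with duration was tested with an exact permutation test over the 720 orderings of the 6 arrays, with Benjamini-Hochberg adjustment over the 25 lists. Genes were named by 6 rules: the 12 highest and 12 lowest differences at 120 min from vehicle; the 4 highest and 4 lowest at each shorter duration; the 5 highest and 5 lowest for 120 min against 60 min and against 5 min; the 6 highest and 6 lowest slopes past the threshold in each fit, or the 3 smallest p-values where none passed; 16 genes fixed by name; and up to 4 members of each list. Symbols of unnamed loci and clones were skipped. List members that passed a trend but fall outside the rule are named as well where few passed, chosen after their values were seen.

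The fits were tested on simulated data with 200 of 12605 genes changed. The simulated spread was that left by the trend over 6 arrays, with no differences between durations beyond the planted change. In the measured arrays such differences add to the spread of the first fit, so its simulated recovery cannot be carried over. For a 2-fold change over the range, 76.5% were recovered for any dmPGE2 against vehicle, 67.5% for the trend over 6 arrays and 55% for the trend among the 5 dmPGE2 arrays. For a 1.5-fold change 0% were recovered by each fit, and for a 4-fold change 95.5%, 94.5% and 92.5% in the same order.

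Alternatives were no filter, a stricter filter that keeps the brightest 25% of probe sets, the mean of a gene's probe sets, leaving out probe sets marked as shared between transcripts, quantile normalisation of the deposited values, and scaling to the median of the housekeeping genes. Others were fold thresholds of 1.5 and 3, eBayes with trend and robust settings, an adjusted p of 0.1, duration as minutes or as rank, leaving out each array, lists summarised by the mean, selections of 50 or 200 genes, and Spearman in place of Pearson correlation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.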

Results

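CD34+ cells, the blood fraction that holds hematopoietic stem and progenitor cells, were thawed from cord blood and incubated for 120 min in all conditions. One array came from cells kept in vehicle throughout. The other 5 came from cells given 10 uM 16,16-dimethyl prostaglandin E2 (dmPGE2), a stabilised analog of prostaglandin E2, for 5, 15, 30, 60 or 120 min, with vehicle for the rest of the 120 min. The treatment labels state a temperature for the 5, 15, 30 and 60 min arrays but none for the 120 min and vehicle arrays. Whether it differed cannot be told from these labels. The study asked whether the whole 120 min of dmPGE2 are needed for the largest response in gene expression or whether a shorter pulse gives as much. Each condition had 1 array, so values per duration have no replicate error. RNA was collected after the incubation, so the time since the end of the dmPGE2 pulse differed between arrays.

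After 120 min of dmPGE2, the cAMP-responsive repressor gene CREM was 20.5-fold higher than in vehicle. SV2C, a synaptic vesicle protein gene, was 21.5-fold higher, the long noncoding RNA LINC00473 21.5-fold, and the dual-specificity phosphatase gene DUSP4 19.6-fold. The other genes among the 12 highest were ECEL1 (16.0-fold), IL11 (14.5-fold), GEM (13.3-fold), BABAM2-AS1 (13.2-fold), MCEMP1 (11.2-fold), the carbonic anhydrase gene CA4 (11.1-fold), the kinase gene SIK1 and the nuclear receptor gene NR4A2 (3.46 log2 each). The lowest was CMPK2, a mitochondrial nucleotide kinase gene, at 9.86-fold below vehicle, then the small GTPase genes GIMAP6 (7.36-fold lower) and GIMAP7 (5.99-fold lower), MDM1 (5.57-fold), TMEM87B (5.56-fold), the polysialyltransferase gene ST8SIA4 (5.48-fold), the transcription factor gene MYCN (5.24-fold), IFT81 (5.03-fold), CFL2 (4.83-fold), PARP8 (4.81-fold), HEATR5B (4.78-fold) and KLF11 (4.75-fold). For MYCN, the 4 other kept probe sets, all dimmer, lay between 0.20 and 0.30 log2 above vehicle, so its lower value rests on 1 probe set. Other kept probe sets stood at 2.51 log2 for SV2C (4.42 for the one used), 1.49 to 4.15 for CREM (4.36), 1.70 for CA4 (3.48), 0.31 for SIK1, -1.03 and -0.83 for ST8SIA4 (-2.45), -0.74 for CFL2 (-2.27) and -0.90 for PARP8 (-2.27). Of the 114 genes named by rule, 53 had another kept probe set. For 36 of the 53 such a probe set showed under 0.5 times the value at 120 min or the opposite sign, the latter for 12, so values given are those of the probe set used. The vehicle values of SV2C (5.82 log2), LINC00473 (5.46), ECEL1 (6.27) and CA4 (5.39) lay under the 6.47 log2 used to keep probe sets, as did the 120 min values of GIMAP6 (6.39), MDM1 (5.62), TMEM87B (6.10), CFL2 (6.02) and PARP8 (6.46). Background was not measured, so the folds of these genes could be too small and their order is uncertain.

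The shorter pulses gave fewer such genes. The number at least 2-fold from vehicle was 13 after 5 min (3 higher, 10 lower), 12 after 15 min (11 higher, 1 lower), 113 after 30 min (46 higher, 67 lower), 209 after 60 min (91 higher, 118 lower) and 936 after 120 min (255 higher, 681 lower). After 5 min the highest genes were GNL3L (1.19 log2 above vehicle), IL11 (1.17), LINC00663 (1.10) and KLF3-AS1 (0.93), with the other kept probe set of KLF3-AS1 at 0.07, and the lowest were the cytokine gene IL1A (-1.16), ELK4 (-1.16, its other kept probe sets -0.38 and -0.05), HEATR5B (-1.08) and MTX2 (-1.08). After 15 min SV2C (1.71), PDLIM3 (1.57), MCEMP1 (1.41) and IL11 (1.39) were highest, and SLA (-0.91), the prostaglandin receptor gene PTGER4 (-0.90), CEP126 (-0.87) and IL6 (-0.83) were lowest. After 30 min the highest were SV2C (3.39), CREM (2.97), EGR4 (2.23) and MCEMP1 (2.08), and the lowest MTX2 (-1.62), CMPK2 (-1.59), LMBRD2 (-1.59) and IL6 (-1.58). After 60 min SV2C (4.33), CREM (3.58), LINC00473 (3.24) and MCEMP1 (2.95) were highest, and NRTN (-2.13), the BMP pathway inhibitor gene SMAD6 (-2.12), TMEM170B (-1.71) and PPARGC1B (-1.63) were lowest. The vehicle values of EGR4 (5.83) and SV2C, the 30 min value of LMBRD2 (6.15) and the 60 min values of NRTN (5.36) and TMEM170B (5.93) lay under 6.47 log2, so these differences and their order are uncertain too.

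Of the 255 genes 2-fold higher at 120 min, 1 was also 2-fold higher after 5 min, 10 after 15 min, 43 after 30 min and 78 after 60 min. The median gene of the 255 had 13.4% of its 120 min log2 difference after 5 min, 19.5% after 15 min, 37.4% after 30 min and 52.1% after 60 min. By 60 min, 47 of them had at least 80% of it and 35 had under 20%. Of the 681 genes 2-fold lower at 120 min, 5, 1, 61 and 93 were 2-fold lower after 5, 15, 30 and 60 min, and the median gene had 26.6%, 16.2%, 49.7% and 50.8% of its 120 min difference. Error on the 120 min array, which picked these genes and sets the 100%, lowers such shares, and error on the shared vehicle array raises them. Picked after 30 min instead, the 100 highest genes had medians of 1.14 log2 after 60 min and 1.64 after 120 min, and the 100 lowest -0.98 and -1.53. The split of higher and lower genes moved with scaling. After quantile normalisation it was 5 higher and 7 lower at 5 min, 54 and 44 at 30 min, 110 and 81 at 60 min and 321 and 476 at 120 min, and after scaling to housekeeping genes it was 64 and 35 at 30 min and 162 and 50 at 60 min. Housekeeping scaling raised the median difference of all genes from vehicle by 0.12 log2 at 30 min and 0.19 log2 at 60 min. Quantile normalisation moved this median from -0.04 to 0.06 log2 at 120 min.

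**Figure D1:**
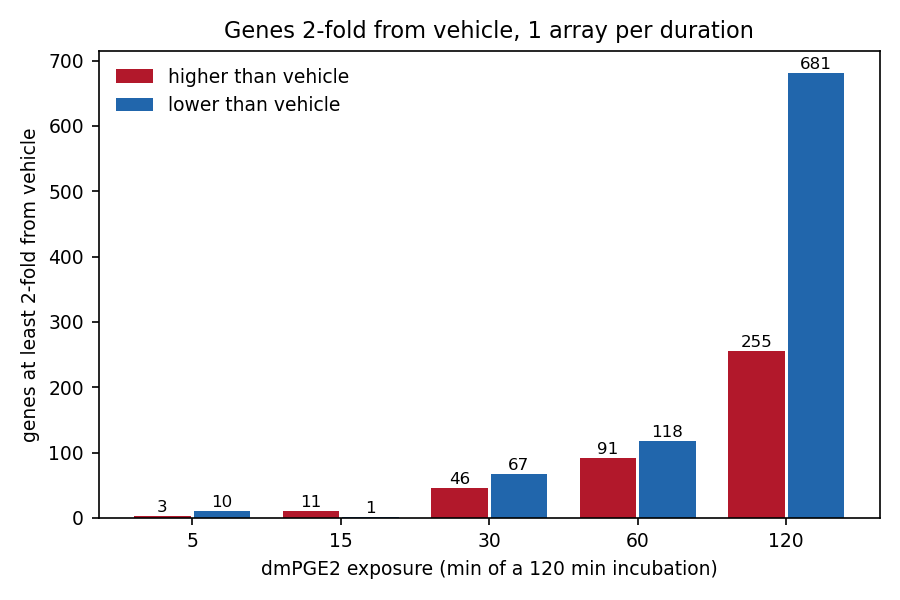
Bars give the number of genes (y axis) at least 2-fold higher (red) or lower (blue) than the vehicle array for each dmPGE2 exposure in minutes (x axis), from 1 array per duration. Higher genes number 3, 11, 46, 91 and 255 and lower genes 10, 1, 67, 118 and 681 from 5 to 120 min.

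The cells given dmPGE2 for all 120 min were set against each shorter pulse. Against 60 min, DUSP4 was 3.39 log2 higher, the GTPase gene GEM 3.16, the phosphatase gene DUSP2 3.07, the cytokine gene IL11 2.88 and SIK1 2.87. The lowest were GIMAP6 (-2.30), CYP2U1 (-1.91), ZBTB44 (-1.83), the kinesin gene KIF3A (-1.81) and CMPK2 (-1.78), and the other kept probe set of CYP2U1 stood at -0.08 log2 from vehicle at 120 min, against -2.06 for the one used. SV2C and PDLIM3 differed by 0.10 and 0.11 log2 between 120 and 60 min. Against 5 min, LINC00473 (4.60), GEM (4.31), DUSP4 (3.95), the chemokine gene CXCL5 (3.79) and BABAM2-AS1 (3.77) were highest, and GIMAP6 (-2.72), CMPK2 (-2.61), GIMAP7 (-2.35), MYCN (-2.06) and the G protein regulator gene RGS19 (-1.93) lowest. The 120 min values of CYP2U1 (5.43 log2) and GIMAP6 (6.39) and the 5 min value of LINC00473 (5.28) lay under 6.47 log2. The differences of these genes and their order are therefore uncertain. In all, 479 genes differed by at least 2-fold between 120 and 5 min (209 higher at 120 min, 270 lower), 593 between 120 and 15 min (173 and 420), 199 between 120 and 30 min (126 and 73) and 203 between 120 and 60 min (80 and 123). Between 30 and 60 min only 9 genes did, 6 higher at 60 min and 3 lower. Against 5 min the split turned, to 243 higher and 218 lower after quantile normalisation and 192 and 167 with the mean of probe sets. The split was 209 and 292 against 15 min after quantile normalisation, and 110 and 108 against 30 min and 67 and 226 against 60 min after housekeeping scaling.

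**Figure D2:**
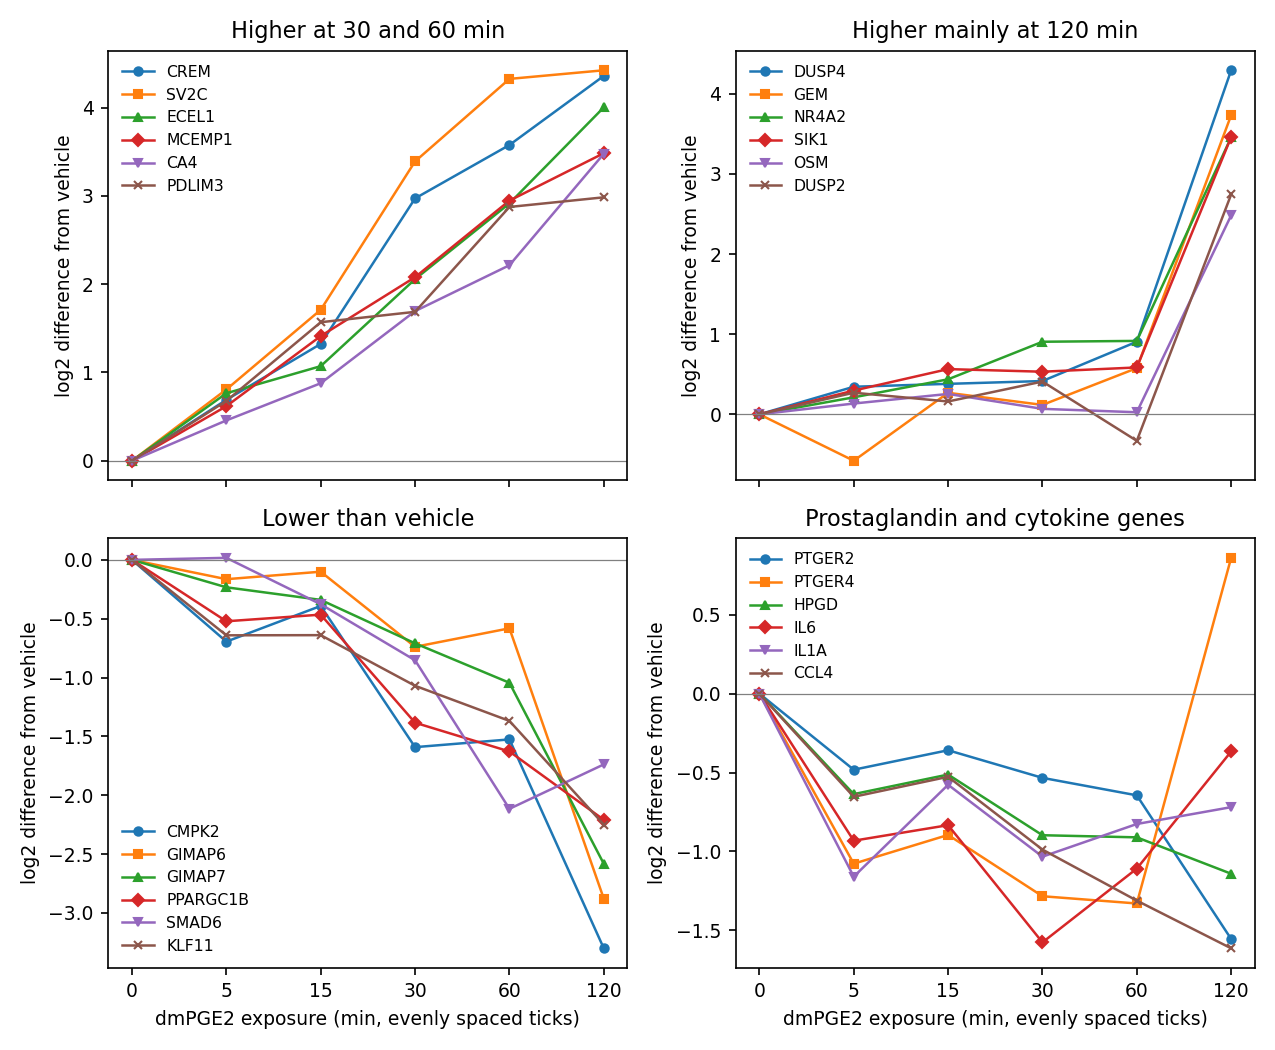
Lines give the log2 difference from vehicle (y axis) of named genes for each dmPGE2 exposure in minutes (x axis, with vehicle at 0 and evenly spaced ticks), with 1 array per point. CREM and SV2C stand at 2.97 and 3.39 after 30 min, whereas DUSP4 and GEM stand at 0.91 and 0.58 after 60 min and at 4.29 and 3.73 after 120 min.

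Over the 6 arrays, expression rose with dmPGE2 duration for SV2C, CREM, LINC00473, ECEL1, MCEMP1 and BABAM2-AS1. SV2C rose by 0.72 log2 per unit of log2 minutes (SE 0.08, n = 6 arrays, limma, Benjamini-Hochberg adjusted p = 0.0155) and CREM by 0.66 (SE 0.07, limma, adjusted p = 0.0155). The slopes of LINC00473, ECEL1, MCEMP1 and BABAM2-AS1 were 0.64, 0.56, 0.52 and 0.50, with limma adjusted p of 0.0394, 0.0155, 0.0155 and 0.026. Among genes past the threshold, the steepest falls were in CMPK2 (slope -0.41), PPARGC1B, a transcriptional coactivator gene (-0.31), MDM1 (-0.31), SMAD6 (-0.31), GIMAP7 (-0.31) and TMEM170B (-0.31), with limma adjusted p from 0.0184 to 0.041. Of 12605 genes, 1658 passed the limma test after Benjamini-Hochberg adjustment, 458 rising and 1200 falling, against 588 and 782 after quantile normalisation and 637 and 388 after housekeeping scaling. DUSP4, GEM, SIK1, NR4A2 and IL11 did not pass (limma adjusted p from 0.0614 to 0.123). Among the alternatives of this fit, DUSP4, GEM and SIK1 passed in 2 and NR4A2 and IL11 in 3. Their lowest limma adjusted p ran from 0.00057 for NR4A2 to 0.0075 for IL11. The count depended on single arrays: it was 8 without the 5 min array, 95 without the 30 min array, 151 without the 120 min array, 446 without vehicle and 487 without the 60 min array. MCEMP1 passed under all 15 alternatives of this fit that gave it a value, with limma adjusted p from 1.24e-05 to 0.0481.

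Among the 5 dmPGE2 arrays alone, the fit that leaves the vehicle array out, LINC00473 rose by 1.07 log2 per unit of log2 minutes (SE 0.15, limma, Benjamini-Hochberg adjusted p = 0.0405). SV2C (slope 0.88), CREM (0.85), BABAM2-AS1 (0.76), CXCL5 (0.74) and ECEL1 (0.72) also rose, with limma adjusted p from 0.0236 to 0.0416. SMAD6 (-0.46), RGS19 (-0.44), the adaptor gene CARD10 (-0.41), PPARGC1B (-0.39), TMEM170B (-0.39) and GIMAP2 (-0.38) fell, with limma adjusted p from 0.0306 to 0.0458. The other kept probe set stood at 0.14 for SMAD6, 0.33 for CARD10 and 0.01 for PPARGC1B at 120 min, against -1.74, -1.79 and -2.21 for those used, so these falls, in either fit, are those of single probe sets. MCEMP1 had the smallest limma adjusted p (0.00376, slope 0.65, SE 0.04). In all, 197 genes passed, 99 rising and 98 falling, and 174 of them were among the 1658 of the fit over 6 arrays. After housekeeping scaling 53 rose and 19 fell. The count was 2 without the 30 min array, 3 without the 15 min array, 15 without the 60 min array and 50 without the 120 min array.

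When the 5 dmPGE2 arrays were set as 1 group against vehicle, the smallest p-values belonged to the nuclear lamina gene LMNB1, the adaptor gene SLA and the small nucleolar RNA SNORA21. At the 5 durations LMNB1 lay between 0.84 and 1.18 log2 from vehicle, SLA between -0.94 and -0.61 and SNORA21 between 0.54 and 0.87. None passed: limma called 0 genes at a Benjamini-Hochberg adjusted p of 0.05, the smallest adjusted p was 0.707, and 505 genes had an unadjusted p under 0.05. Differences between durations count as spread in this fit.

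Genes known to respond to cAMP, the second messenger of the prostaglandin receptors encoded by PTGER2 and PTGER4, stood out at 120 min. The median of the 27 measured members was -0.00, 0.16, 0.18, 0.32 and 1.62 log2 from vehicle after 5, 15, 30, 60 and 120 min, and the last 4 medians exceeded all 10000 random lists. Over the alternatives these 4 ran from 0.07 to 0.23, 0.09 to 0.36, 0.15 to 0.52 and 0.93 to 1.78, each lowest without probe sets marked as shared. The 95% interval of the median held 0 after 15 min (-0.07 to 0.44), 30 min (-0.15 to 0.53) and 60 min (-0.05 to 0.91) but not after 120 min (0.54 to 2.97). At 120 min 16 of the 27 were at least 2-fold higher and 0 lower, among them CREM (4.36), DUSP4 (4.29), GEM (3.73), SIK1 (3.46), NR4A2 (3.46), NR4A3 (2.98), the phosphodiesterase genes PDE4B (2.97) and PDE4D (1.24) and NR4A1 (1.62). After 60 min 5 were, and PDE4B stood at 0.53, PDE4D at -0.07 and NR4A1 at 0.39. PTGS2, the inducible cyclooxygenase gene and a member of the list, stood at -0.85 log2 from vehicle after 5 min and -0.20 after 120 min. With limma, 6 of the 27 rose over the 6 arrays (7 adjusted over the list alone) and 0 fell: CREM, NR4A3, the transcription factor gene FOSL2, the phosphodiesterase gene PDE4A, AKAP12 and the glucose transporter gene SLC2A3, with adjusted p from 0.0155 to 0.0332. CREM, PDE4A, AKAP12 and SLC2A3 also rose among the 5 dmPGE2 arrays, 4 in all (14 adjusted over the list alone). At 120 min the other kept probe set of AKAP12 stood at -0.71, against 1.66, and the 2 of PDE4A at 0.30, against 2.17. Here and below, list members outside the naming rule that passed were named after their values were seen.

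Regulators that damp MAP kinase signalling had a median 0.67 log2 above vehicle at 120 min over 11 measured members (95% interval -0.58 to 2.74), above all random lists. DUSP4, DUSP2 (2.74) and SPRY1 (2.43, its other kept probe set 1.04) were higher and DUSP6 was lower (-1.04), and 2 of the 11, DUSP5 (0.67) and ERRFI1 (0.97), rose over the 6 arrays by limma (2 adjusted over the list alone). Among the 22 immediate-early genes, the median was 0.37 at 120 min (0.63 without shared probe sets), 6 were 2-fold higher and 1 lower. FOSB (2.19, limma adjusted p = 0.0259) and MAFF (0.62, 0.0404) rose over the 6 arrays (2 adjusted over the list alone), and FOS (1.82), ATF3 (1.40), CSRNP1 (1.13) and EGR1 (0.79) did not pass. Other kept probe sets stood at 1.61 for MAFF, 0.75 for ATF3, and 0.64 and 2.16 for EGR1 at 120 min. The DUSP4 and DUSP2 values after 60 min were 0.91 and -0.33.

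Cytokine, chemokine and growth factor genes went both ways. After 5 min the median of the 20 measured members was -0.25 log2 (95% interval -0.63 to 0.12), at percentile 0.02 of 10000 random lists, and after 120 min it was 0.36, at percentile 99.97 (0.24 to 0.69 over the alternatives). At 120 min 8 were 2-fold higher, with IL11 (3.86), LIF (3.12) and OSM (2.48, its other kept probe set 0.60) at the top, and 2 were lower. The chemokine gene CCL4 (-1.61, limma adjusted p = 0.0168) and TNF (-1.26, 0.0355) fell over the 6 arrays (2 adjusted over the list alone). IL11 was at least 0.98 log2 above vehicle at every duration, and its other kept probe set at least 0.51. IL6 stood at -1.58 log2 after 30 min and -0.37 after 120 min. NF-kB target genes had medians of -0.20, -0.27, -0.10, -0.26 and -0.07 over the 5 durations, the last of which was 0.06 after quantile normalisation. The inhibitor gene NFKBIA (-0.79 at 120 min, limma adjusted p = 0.0371) and TNFAIP2 (-0.68, 0.0439) fell and NFKB1 (0.63, 0.035) rose over the 6 arrays, out of 13 members (3 adjusted over the list alone). The other kept probe set of NFKBIA stood at -0.18 and that of TNFAIP2 at 0.21.

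In the prostaglandin list, PTGER2 (-1.56 at 120 min) and HPGD (-1.14, its other kept probe sets -0.88 to -0.44), the gene of the enzyme that inactivates prostaglandins, fell over the 6 arrays (limma adjusted p = 0.0418 and 0.0196), and 4 of the 12 members passed adjusted over the list alone, 1 of them rising. PTGER4 stood at -1.08, -0.90, -1.28 and -1.33 log2 from vehicle after 5, 15, 30 and 60 min and at 0.86 after 120 min, on 1 probe set bright enough to keep, and no trend passed (limma adjusted p = 0.936). The list median at 120 min was 0.06, and -0.20 to 0.13 over the alternatives. Homing and adhesion genes had a median of -0.03 over 20 members (0.03 after quantile normalisation and 0.04 after housekeeping scaling), with S1PR1 (2.16) and the chemokine receptor gene CXCR4 (1.90) 2-fold higher, MMP9 (1.70) rising (limma adjusted p = 0.0332) and the integrin gene ITGA4 (-1.52, 0.0318) and MMP2 (-0.75, 0.0368) falling (3 adjusted over the list alone). CXCR4 was 0.29 log2 above vehicle after 60 min, and its other kept probe sets stood at 3.21 and 3.01 after 120 min.

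Stem and progenitor genes had medians of -0.05, -0.09, -0.20, -0.23 and -0.38 log2 over the 5 durations, the last at percentile 2.15 of the random lists and -0.21 after quantile normalisation. Of 20 members 5 fell over the 6 arrays by limma and 0 rose (8 passed adjusted over the list alone, 1 of them rising), namely ERG (-1.16, limma adjusted p = 0.0223), MYB (-1.13, 0.0314), PROM1 (-0.62, 0.0328), MECOM (-0.71, 0.0465) and MEIS1 (-0.60, 0.0395). Among the 5 dmPGE2 arrays 0 of the 20 passed over all genes (3 adjusted over the list alone, 1 of them rising). In that fit 0 members of the MAP kinase, immediate-early, cytokine, NF-kB and prostaglandin lists passed over all genes either. The other kept probe set of MECOM stood at -0.02, that of MYB at -0.29 and the 3 of ERG between -0.52 and -0.45, so these values are larger than the other probe sets show. LMO2 (-1.10, its other kept probe set -1.65) did not pass, and CD34 itself stood at -0.20 at 120 min. Interferon response genes had a median of -0.40 at 120 min, against a mean of 0.03, with ISG15 (1.81, limma adjusted p = 0.0194), MX2 (1.24, 0.0307) and MX1 (0.89, 0.0268) rising and IFIT1 (-0.43, 0.0433) falling (8 passed adjusted over the list alone, 4 of them rising). IFIT3 (-1.18, its other kept probe set -0.10) and IRF7 (1.03) did not pass. On the 120 min array, the bacterial controls added at hybridisation were 0.516 log2 brighter than on the vehicle array.

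Among WNT and beta-catenin targets the median at 120 min was 0.23 over 10 members (0.69 over the 2 left by the stricter filter), BAMBI (1.41) rose (limma adjusted p = 0.0432) and LEF1 (-0.51) fell (0.0416; 2 adjusted over the list alone), and AXIN2 (0.38) and CCND1 (0.46) did not pass. The other kept probe set of LEF1 stood at 0.41. Hypoxia and glycolysis genes had a median of 0.26 (0.23 to 0.51 over the alternatives), 4 of 14 were 2-fold higher, namely ANKRD37 (2.01), SLC2A1 (1.83), VEGFA (1.31) and PFKFB3 (1.17), and 0 passed over all genes (6 adjusted over the list alone, 5 of them rising). Survival and apoptosis genes had a median of -0.00 (0.17 after quantile normalisation, 0.07 after housekeeping scaling and 0.31 without shared probe sets), with BCL2L11 at 2.02 and BIRC5 at -0.00, and BCL2 (0.63, its other kept probe sets 0.13 and 0.29, limma adjusted p = 0.0317) was the 1 of 17 that rose (1 adjusted over the list alone). The median of 24 cell cycle genes was -0.12 but 0.05 after quantile normalisation. CDKN1C (-1.09, its other kept probe sets -0.95 to -0.23, limma adjusted p = 0.0202) and MCM3 (-0.77, 0.0328) fell, AURKA (0.92, 0.0482) rose (3 adjusted over the list alone), and CDKN1A (1.93) and CCNE2 (-1.24) did not pass. Heat shock and stress genes had a median of 0.14 (0.28 after quantile normalisation), with HMOX1 at 1.12, and DDIT4 (0.62, limma adjusted p = 0.0364) rose (0 adjusted over the list alone). Cholesterol synthesis genes had 0.25 (0.40 after quantile normalisation and -0.00 without shared probe sets), with SQLE at -1.13, and DHCR7 (0.88, limma adjusted p = 0.0213) rose over the 6 arrays (1 adjusted over the list alone) and SC5D (1.48, 0.0278) among the 5 dmPGE2 arrays.

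For markers of cell types that the CD34+ fraction could hold, medians at 120 min were 0.20 for erythroid, 0.16 for megakaryocyte, 0.11 for monocyte, 0.27 for neutrophil, 0.30 for T and NK cell, 0.02 for B cell, 0.24 for mast cell and basophil, and 0.11 for endothelial markers. Over the alternatives they ran from 0.15 to 0.35 for megakaryocyte, 0.04 to 0.22 for monocyte, 0.09 to 0.36 for neutrophil, 0.25 to 1.196 for T and NK cell, -0.68 to 0.14 for B cell, 0.24 to 0.37 for mast cell and 0.09 to 0.23 for endothelial markers. The stricter filter gave the 1.196 and -0.68 from 2 genes each, the endothelial 0.23 from 1 gene and the neutrophil 0.09 from 3 genes. Of all 25 lists, 17 had a 95% interval of the median at 120 min that held 0. The 8 others were the cAMP, immediate-early, cytokine, cell cycle, stem and progenitor, megakaryocyte, T and NK cell and endothelial lists. This interval is taken over member genes on 1 pair of arrays. The medians of the T and NK cell (percentile 92.4), megakaryocyte (81.2), endothelial (69.7) and cell cycle lists (45.7) lay within the middle 95% of the random lists. The members at least 2-fold from vehicle at some duration were CA2 (2.28), HEMGN (-1.55, its other kept probe set -0.09) and KLF1 (-1.26 after 60 min) among erythroid markers, GZMB (1.81) among T and NK cell markers and IL1RL1 (1.92) among mast cell markers, and none of the 5 passed a limma trend. The 120 min value of HEMGN (6.24 log2) lay under 6.47 log2, so its difference is uncertain. ITGA2B (0.54) rose (limma adjusted p = 0.0332; 1 adjusted over the list alone), and IGHM (-0.78) and MS4A1 (-0.75) fell (0.0431 and 0.0335; 4 B cell markers adjusted over the list alone, 1 of them rising), and 0 erythroid, monocyte, neutrophil, T and NK cell, mast cell or endothelial markers passed over the 6 arrays (0 adjusted over the list alone in each). The other kept probe sets stood at -0.27 and -0.05 for ITGA2B, -0.48, 0.00 and 0.37 for IGHM, and -0.24 and 0.05 for MS4A1, so their probe sets differ in direction. The calls passed in 8 of 15, 7 of 15 and 6 of 14 alternatives. Values at 120 min of those named by rule were -0.69 for PLEK, -0.44 for VCAN, 0.40 for CD14, 0.51 for LCN2, 0.46 for AZU1, 0.23 for PECAM1 (its other kept probe sets -0.70 to -0.04) and 0.15 for VWF. Housekeeping genes had a median of 0.00, with IPO8 at -1.08 (0 passing, 3 adjusted over the list alone, 1 of them rising), and ribosomal protein genes a median of -0.00 (0.07 after housekeeping scaling), with RPS23 at -0.35 (its other kept probe set 0.53) and RPL19 at 0.11 (0 passing, 0 adjusted over the list alone).

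**Figure D3:**
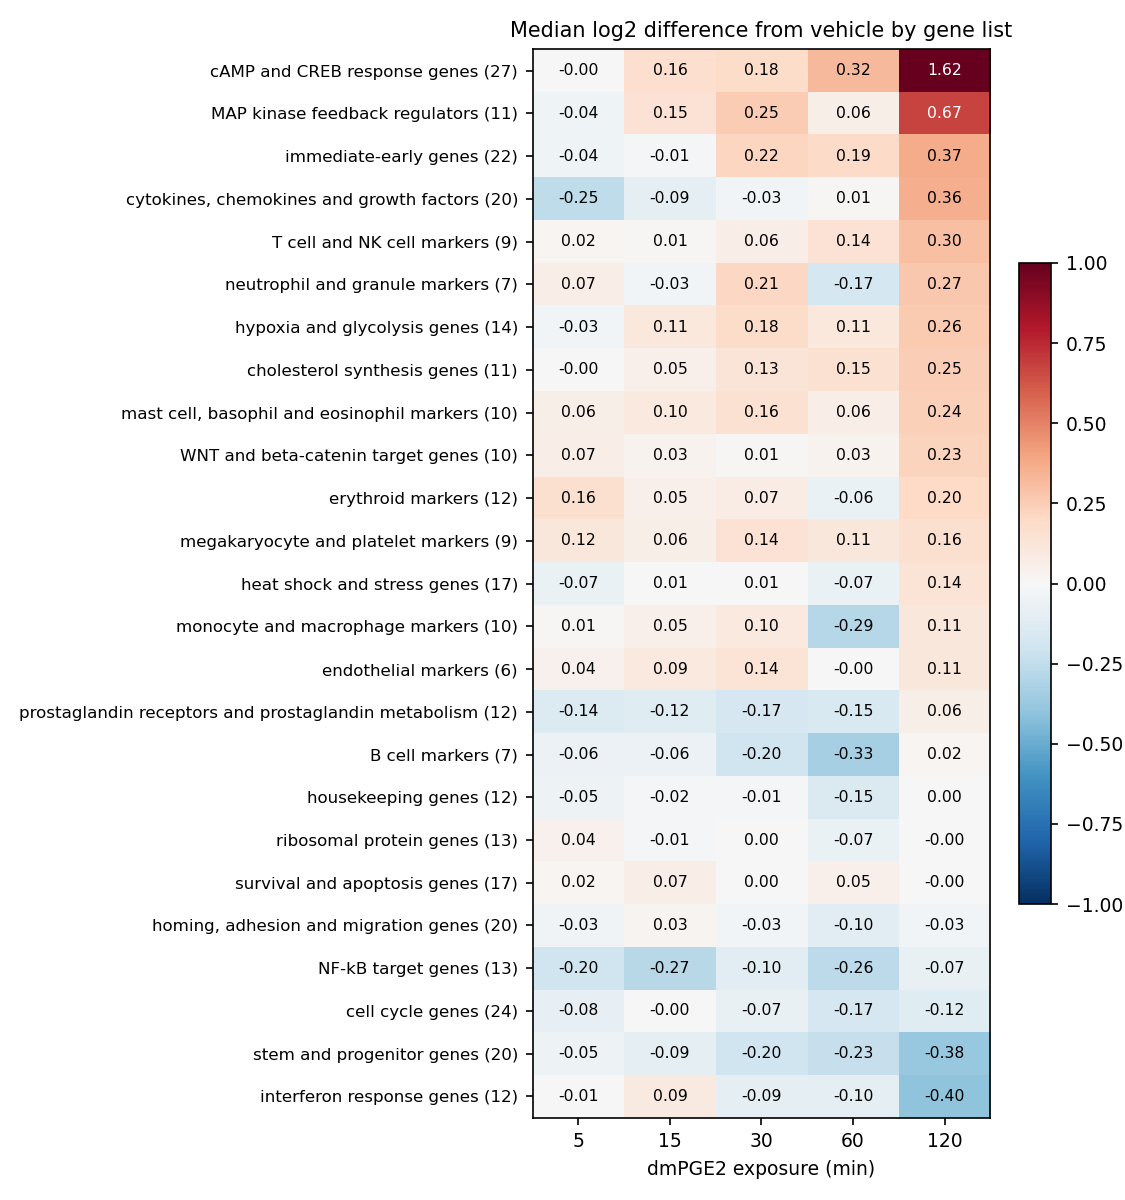
Each cell gives the median log2 difference from vehicle over the measured members of a gene list (rows, with the number of members in brackets) at each dmPGE2 exposure in minutes (columns), with colour held at -1 and 1. The cAMP and CREB response genes go from -0.00 at 5 min to 1.62 at 120 min, and the stem and progenitor genes from -0.05 to -0.38.

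The mean of the cAMP list followed the order of the durations over the 6 arrays (Spearman rho 1, exact permutation p = 0.00278, adjusted p = 0.0347 over 25 lists by Benjamini-Hochberg), and so did that of the T and NK cell markers with the same values. No smaller p can be reached by rho with 6 arrays, and 1 list alone at it would not pass over 25 lists. The cAMP call here thus depends on the T and NK cell markers reaching it as well. With the mean of probe sets neither passed (rho 0.943, exact permutation, adjusted p = 0.0595), nor did the T and NK cell markers without shared probe sets (adjusted p = 0.104). Pearson's r was 0.765 (exact permutation p = 0.0792, adjusted p = 0.205) and 0.724 (exact permutation p = 0.101, adjusted p = 0.208), but both passed by r with duration as minutes (adjusted p = 0.0174) or as rank (0.0347). Without the 2 arrays farthest from the median duration, r was 0.999 for the cAMP list and 0.797 for the T and NK cell markers. The mean of the T and NK cell markers lay 0.013, 0.0267, 0.0278, 0.145 and 0.424 log2 above vehicle from 5 to 120 min. Its order thus rests on a very small step between 15 and 30 min, and GZMB was the only 1 of its 9 members 2-fold higher at 120 min. By r, 0 of the 25 lists passed after adjustment and 3 had an unadjusted p under 0.05: stem and progenitor genes (r = -0.932, rho = -0.943, exact permutation p = 0.0111 and 0.0167, adjusted p = 0.205 and 0.0833), cholesterol synthesis genes (r = 0.853, rho = 0.943, exact permutation p = 0.0319 and 0.0167, adjusted p = 0.205 and 0.0833) and housekeeping genes (r = -0.825, rho = -0.657, exact permutation p = 0.0458 and 0.175, adjusted p = 0.205 and 0.292). Without the 2 farthest arrays r was -0.715, 0.974 and -0.923 for these 3 lists.

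Genes picked at one duration were measured at the others. The pick favours the duration it was made at, and all differences share the vehicle array, so error in that array carries over. The 100 genes highest after 60 min had a median of 1.22 log2 after 60 min and 1.65 after 120 min. The 100 lowest after 60 min had -1.20 and -1.45. Picked after 120 min, the 100 highest had 2.15 there and 1.02 after 60 min, and the 100 lowest -1.81 and -0.90. Picked after 30 min, the 100 highest had 0.97 after 30 min, 1.14 after 60 min and 1.64 after 120 min. For the 100 highest after 5 min, the median was 0.58 after 5 min, 0.43 after 15 min and 0.66 after 120 min.

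Differences with no array in common were compared across the 12605 genes, which are not independent replicates. The difference of 30 min from vehicle had a Pearson correlation of 0.46 across genes with the further difference of 120 min from 60 min. That of 15 min from vehicle had 0.22 with 60 min minus 30 min, and that of 5 min had 0.52 with 30 min minus 15 min but -0.21 with 60 min minus 30 min. Over the 10 such pairs the correlation ran from -0.21 to 0.52. Differences from the shared vehicle array correlated between 0.50 and 0.83, where unchanged groups simulated against the same array gave 0.50. The covariance was 0.16 for 60 with 120 min against 0.03 simulated, and 0.02 for 5 with 15 min against 0.03. The simulated correlation of 0.50 follows from equal spread on the arrays alone. The simulated spread was that left around the trend among the 5 dmPGE2 arrays, so departures from that line enter it. The simulated covariance of 0.03 may therefore be too high for unchanged groups. Of the 91 genes 2-fold higher after 60 min, 78 were so after 120 min, where independent lists would share 1.84, and of 118 lower genes 93 were, against 6.38. The single vehicle array could not be split, so part of the excess may come from it.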

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

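The tests of the value spread, of the hybridisation level and of short-lived transcripts were chosen only after the result was seen. The bacterial controls added at hybridisation, which no comparison uses, were 0.516 log2 brighter on the 120 min array than on the vehicle array. Probe sets without a gene symbol also carried signal that no comparison uses: 61 of 4100 bright enough to keep were at least 2-fold higher than vehicle at 120 min, 303 were lower, and the highest stood 6.89 log2 above vehicle.

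More genes were lower than higher at 120 min, 681 against 255. Brighter hybridisation stays open. Against it, the bacterial controls were brighter after 5 min (10.8 log2) than after 60 min (10.7), but the 681 genes were lower after 60 min, by a median of -0.29 (95% bootstrap interval -0.32 to -0.25). With it, the controls were dimmest on the vehicle array (10.5) and brightest on the 120 min array (11.02), and the genes had a median of -0.35 after 5 min but -0.21 after 15 min, where the controls were dimmer. The spread of values on the 120 min array stays open as well, since quantile normalisation left 59.7% of 2-fold genes lower (Wilson interval 56.3 to 63.1), between the bounds of 55% and 60% set for and against it. So does signal lost by single probe sets. The other probe sets of the lower genes had a median of -0.43 (interval -0.51 to -0.33), beyond the -0.25 that such loss allows but reaching both sides of the -0.5 set against it, and 270 of 344 genes were below vehicle by them. Here and below, intervals are taken over genes and hold no error between arrays.

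A set of 84 genes was at least 2-fold higher at 120 min but under 1.5-fold higher at 60 min, with GEM, SIK1, PDE4B, DUSP2 and OSM at the top. Error of single probe sets on the 120 min array was not excluded at the bound set, because the other probe sets of 29 of these genes had a median of 0.67 (interval 0.47 to 1.04) against a bound of 0.5, although 28 of the 29 lay above vehicle. A candidate explanation is that such transcripts are short-lived and decay once the pulse ends. Among the 255 higher genes, the 9 immediate-early and MAP kinase feedback genes had a median of 18.7% of their 120 min difference at 60 min and the other 246 had 54.7%, a difference of -36.0 points. This leaves the explanation open, because 7 of the 9 belong to the 84 genes that prompted the test, and the 15 cAMP list members in neither list also had a low median, 23.9%. The 120 min condition is also the only one with no vehicle period after dmPGE2 and has 1 array, so duration, time since removal and the array itself were not separated by this design.

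As a check against chance, the durations were reordered over the arrays. For the trend over 6 arrays, 3 of 100 orderings, the real one included, gave as many as the 1658 genes called, so chance order of the arrays can be excluded at 0.05 among the orderings drawn, but the highest other ordering gave 3101. The check cannot tell dmPGE2 from a technical difference that follows the same order. One such value is the mean of the poly-A controls, which rose at each step from 3.68 log2 on vehicle to 3.89 at 120 min. For the trend among the 5 dmPGE2 arrays, 3 of 100 gave as many as 197 and the highest other gave 1264. For vehicle against the 5 dmPGE2 arrays the fit called 0 genes, so the check decides nothing: 6 of 6 arrays set apart in turn had to give as many, and 6 splits are too few for a share under 0.05. The highest other was 466, with the 120 min array apart.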

How the results depend on the processing

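No paired analysis was possible because each condition has 1 array. Of the 248 values of the main results under other choices, 161 stayed within 1.5 times a count or within the 95% interval of a value, 77 moved beyond that, 7 counts went to 0 and 3 counts of 0 rose above it. The counts among the 248 pool both directions, so they have no sign to change. None of the other values changed sign where the value was called. The split behind the counts did turn with housekeeping scaling. At 60 min it went from 91 higher and 118 lower to 162 and 50. For the trend over 6 arrays it went from 458 rising and 1200 falling to 637 and 388. The cause of such moves was not tested except where fewer genes were tested, fewer arrays fitted or the threshold itself changed. Counts of 2-fold genes from vehicle at 5, 15, 30, 60 and 120 min were 202, 93, 839, 1235 and 2883 at 1.5-fold and 1, 2, 15, 37 and 211 at 3-fold. With the stricter filter, which tests fewer genes, they were 5, 55, 107 and 600 from 15 min on, and 8 at 5 min without probe sets marked as shared. Against 120 min they were 1855, 2259, 930 and 1086 for 5, 15, 30 and 60 min at 1.5-fold, 107, 112, 46 and 43 at 3-fold, and 284, 379 and 123 for 5, 15 and 30 min with the stricter filter.

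The trend over 6 arrays called 1003 genes with the stricter filter, 1025 with housekeeping scaling, 3143 at an adjusted p of 0.1, 3339 with duration as minutes and 2952 as rank, and 8 to 1674 with an array left out. The trend among the 5 dmPGE2 arrays called 299 without filter, 32 with the stricter filter, 366 with the mean of probe sets, 305 with quantile normalisation, 72 with housekeeping scaling, 320 with trend and robust eBayes, 1190 at an adjusted p of 0.1, 1688 as minutes, 875 as rank, and 2 to 204 with an array left out. Any dmPGE2 against vehicle called 0 genes by limma in every setting, with 203 to 964 genes at an unadjusted p under 0.05. Lists past the threshold by r, 0 in the report, were 6 with housekeeping scaling, 5 as minutes and 2 as rank. By rho, 2 in the report, they were 0 with the mean of probe sets, 9 with quantile normalisation and 10 with housekeeping scaling, and 0 with any 1 array left out. With 5 arrays a list could pass by rho only if many of the 25 lists reached the smallest possible p together. The cAMP list median stayed positive at 15 to 120 min, from 0.93 to 1.78 at 120 min.

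Genes picked highest at 60 min had a median at 120 min of 1.18 with the stricter filter, 1.78 with quantile normalisation, 2.14 over 50 and 1.22 over 200 genes. Those picked highest at 120 min had at 60 min 0.76, 1.21 with housekeeping scaling, 1.21 over 50 and 0.79 over 200. The lowest at 60 min had at 120 min -1.24 with the stricter filter and -1.24 over 200, and the lowest at 120 min had at 60 min -0.79 with that filter, -0.71 with housekeeping scaling and -1.06 over 50. Picked at 30 min, the highest had at 60 min 0.92 with the filter, 1.33 with housekeeping scaling, 1.66 over 50 and 0.86 over 200, and the lowest -0.83, -0.79 with housekeeping scaling and -0.87 over 200. Correlations of differences without a common array were 0.45 without filter and 0.50 with quantile normalisation for 5 min with 30 minus 15 min. They were 0.17 without filter, 0.24 with the stricter filter and 0.17 by Spearman for 15 min with 60 minus 30 min, and 0.41 without filter for 30 min with 120 minus 60 min. Of 613 values of 114 named genes at 120 min, 557 moved by less than 0.19 log2, the SD of the 15 min minus 5 min differences. Much of this was fixed by the settings. The filters keep the same probe set, and housekeeping scaling shifted all genes by 0.07 log2. A gene with 1 kept probe set cannot move with the mean of probe sets. Of the 53 named genes with another kept probe set, 36 had one under 0.5 times the value or of opposite sign. The 24 steepest slopes among those past the threshold of the 2 trends kept their sign in all 327 alternatives but lost the threshold in 73. Without probe sets marked as shared, KLF3-AS1 (-0.0413) and MYCN (0.30) reversed, as did the slope of MYCN (0.04 against -0.28), since another probe set then stands for them, and the cell cycle median reversed to 0.0477 with quantile normalisation. Of 19775 genes, 12605 passed the filter, so those with dim signal were tested only without it, and 1 array per duration gives no error for a single duration.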

Other observations

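Some genes outside the lists were looked at after their values were seen. GIMAP1 (-1.32 log2 at 120 min, limma adjusted p = 0.0451 for the trend over 6 arrays) and GIMAP2 (-1.88, limma adjusted p = 0.0267) fell, GIMAP6 (-2.88, limma adjusted p = 0.0871) did not pass, and GIMAP5 stood at 0.17. At 120 min HEY1 stood at 2.45 and HES1 at -1.05, and CXCL1, CXCL2, CXCL3 and IL1B at 1.37, 1.28, 1.24 and -0.31. At 60 min CXCL1, CXCL2 and CXCL3 stood at 0.15, -0.71 and 0.00.

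The first principal component of the 12605 genes held 69.8% of the variance and placed the arrays at -25.1 (vehicle), -14.9 (15 min), -11.3 (5 min), 4.64 (30 min), 8.76 (60 min) and 37.9 (120 min), so the 5 and 15 min arrays stood out of order. The standard deviation of all values was 2.45 log2 on the vehicle array and 2.36 on the 120 min array. From vehicle to 120 min in order of duration, the 3' minus 5' difference of the ACTB control probe sets was 5.12, 5.34, 5.00, 4.98, 4.67 and 4.77 log2 and the mean of the poly-A controls 3.68, 3.74, 3.75, 3.79, 3.81 and 3.89.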
